A study of Corynebacterium glutamicum R with 6 samples.

How the data were processed

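Transcript levels were measured in Corynebacterium glutamicum R, a soil bacterium used to make amino acids and organic acids, in 3 samples of the wild-type strain and 3 of a strain labelled as lacking gntR1. Per the labels' protocols, cultures grew with air in a rich medium with 2% glucose and were harvested in exponential growth at an optical density of 2, and 10 µg of total RNA per sample was copied into cDNA carrying the dye Cy3. Each sample was hybridised to 1 array of 1 colour. The sample labels and the series title name gntR1 as the deleted gene, whereas the series' design text names rshA. The groups here follow the sample labels. The design text speaks of 3 independent experiments, without saying how cultures were kept apart, so p-values measure the spread between these samples.

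The deposited scanner files hold spot intensity values written by Agilent Feature Extraction, version 10.5.1.1 per the file headers and version 10.5.5.1 per the submitters' processing notes. The background-corrected signal in them is on a linear scale and not normalised between arrays. The authors' deposited series matrix holds log2 values. Set against the scanner values it had a slope of 1.00 on all 6 arrays and a median of 0.0000 in each column. For the probes followed below, its fold changes differed by 1 constant from those of log2 spot averages with marked spots kept. It is therefore the mean log2 processed signal of a probe's spots, marked spots included, minus the array's median.

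Each array has 45220 spots, of which 43803 are not controls. By the form of their names the probes fall into 3278 probes with a plain number (called gene probes here, with 2 to 3 spots each), 18462 forward and 18449 reverse probes of a numbered series (called tiling probes, with 1 spot each) and 15 probes whose names carry "ic", with 10 spots each. The meaning of "ic" is not given in the sources used here. The files do not pair probe identifiers with gene names. Of the 3278 gene probe identifiers, 0 matched the reference gene table, which lists 3079 genes of another strain and holds neither gntR1 nor rshA as a symbol. The 24 gene lists fixed before the data were examined, and the named genes of the rule that rest on a symbol, could therefore not be used, and no probe is given a gene name. At most 2 identifiers that rose and 2 that fell are printed. No coordinates are used.

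Signals were taken to log2, each array's 75th percentile over spots that are not controls was subtracted, spots with an outlier mark were left out, and the spots of a probe were averaged. A probe was tested when at least a share of 0.5 of its spots was well above background on all 3 arrays of at least 1 group. Mutant and wild type were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. A probe not well above background on any array of a group has only a bound there. The fold is then given as at least the bright group's mean over a mean for the dim group. That mean takes, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The rule for named probes, fixed before the data were examined, took up to 12 called probes per direction with the most extreme fold change among those whose arrays did not overlap between groups. Values of the "ic" probes were compared with an exact permutation test, whose smallest possible p with 3 against 3 arrays is 0.1.

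On simulated data with the real probes' levels, slide effects and spread, 200 of 3197 gene probes were changed by a known fold. Without a slide block, limma recovered 16.4% of those changed 2-fold, 80.6% of those changed 4-fold and 93.9% of those changed 8-fold, with 0 false calls. With the block it recovered 68.7%, 88.1% and 93.9%, with 6 false calls. The simulation gave 127 calls without and 173 with the block, against 27 and 53 in the data. More calls make the adjusted threshold less strict, so recovery in the data may be lower. The simulated spread was drawn separately for each probe, without shifts shared over an array, so the false calls may be too few.

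The 6 arrays lie on 3 slides, each scanned at its own time and each holding 1 array of either group with the same experiment number, so slide and replicate number are 1 block. Deviations from the group means correlated on the same slide by 0.68, 0.41 and 0.76 over 2964 gene probes, which are not independent replicates. By this measure and the shared slides the numbers pair the samples. The fit without the block is the main one, as fixed before the data were examined, and the blocked fit is an alternative. The other alternatives were normexp background correction with an offset of 50, quantile normalisation, the array median, no filter and a stricter filter on dim probes, marked spots kept, eBayes with trend and robust, the authors' series matrix, and each array left out in turn. For normexp the median spot signal stood in for the mean signal. The test of the tiling probes, the grouping of probes by number (gaps of at most 5, with 2 and 10 as alternatives) and the omission of slide 3 were added after the data had been seen.

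Spots well above background made up 79.0% to 99.5% of non-control spots per array, and 0 were saturated. On slide 3, 4350 (9.93%) and 4609 (10.5%) non-control spots of the wild-type and mutant array carried an outlier mark, against 48 to 80 on each other array. The number of arrays limits the precision.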

Results

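Transcript levels of 3278 gene probes and 36911 tiling probes were compared between 3 wild-type arrays and 3 arrays of the strain labelled as the gntR1 deletion mutant of Corynebacterium glutamicum R. GntR1 is known as a regulator of the GntR family that acts on gluconate use and central sugar metabolism in this genus. The comparison asks which transcripts differ between the strains in exponential growth on glucose. Before scaling, the 75th percentile of the signal ranged from 1812 on the wild-type array of slide 3 to 4004 on that of slide 2. Levels below are log2 signals relative to that percentile of the same array.

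A single gene probe was lost in the mutant. CGR2615 stood at 1.03 ± 0.16 (SD, n = 3) in the wild type and at -9.08 ± 0.46 (SD, n = 3) in the mutant, where it was not well above background on any array. It was at least 412-fold lower (limma adjusted p = 1.83e-06). Its signal was 8297, 8944 and 3258 on the wild-type arrays and 6.55, 5.04 and 4.79 on the mutant arrays. The files do not pair identifiers with gene names, so whether this probe reads gntR1, or rshA as the design text has it, is not settled here, and the deletion itself could not be checked by name. No gene probe went the other way, from background in the wild type to a measured level in the mutant (0 probes). The gene probes 1 and 2 numbers before CGR2615 differed by -0.20 (SE 0.22) and -0.30 (SE 0.21), and the probe 1 number after it by -1.05 (SE 0.26). None of these 3 passed the test.

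**Figure D1:**
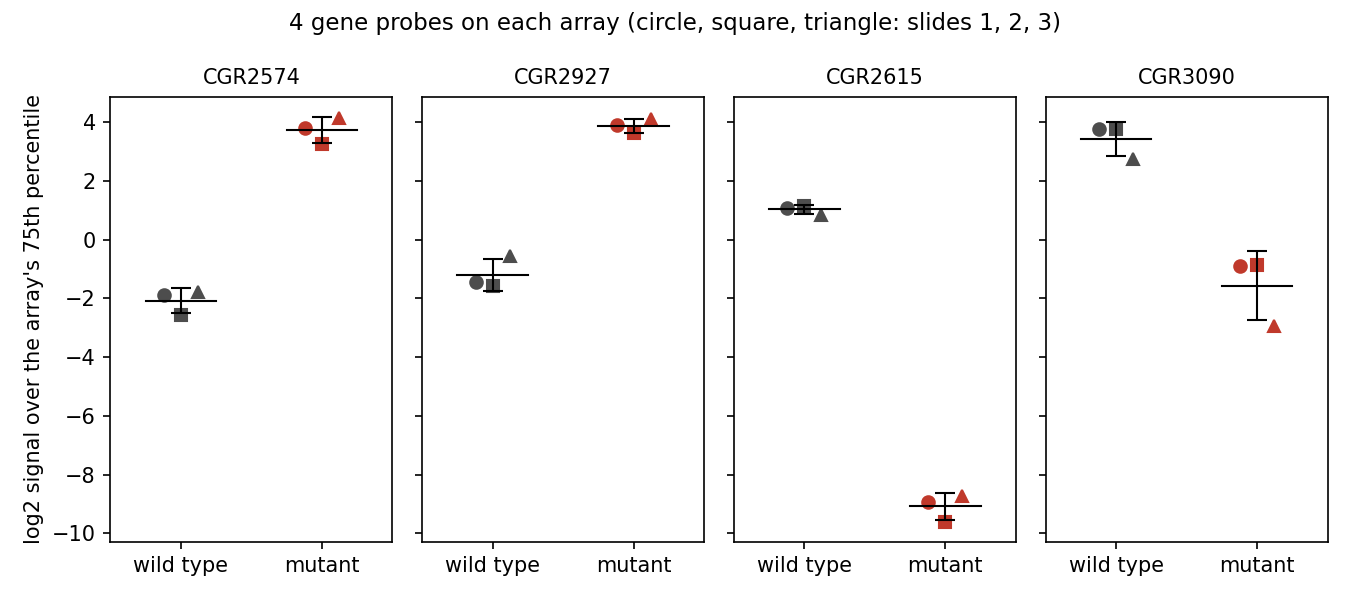
Log2 signal relative to the array's 75th percentile (y axis) of 4 gene probes on the wild-type (grey) and mutant (red) arrays, with circle, square and triangle for slides 1, 2 and 3, and bars for the mean and SD of 3 arrays. CGR2574 and CGR2927 lie higher on all mutant arrays, and CGR2615 and CGR3090 lie lower, with CGR2615 not well above background on the mutant arrays.

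Of the called gene probes that could still be measured in both strains, CGR2574 changed most. The order of CGR2927 and CGR3090, which came next, depended on the processing. With quantile normalisation their log2 fold changes were 5.05 and -5.17. CGR2574 rose from -2.07 ± 0.43 to 3.74 ± 0.45 (SD, n = 3 each), a log2 fold change of 5.81 (SE 0.32) or 56.1-fold (limma adjusted p = 1.82e-04). CGR2927 rose from -1.20 ± 0.55 to 3.87 ± 0.24 (SD, n = 3 each), by 5.07 (SE 0.31) or 33.7-fold (limma adjusted p = 2.99e-04). CGR3090 fell from 3.43 ± 0.58 to -1.56 ± 1.19 (SD, n = 3 each), a log2 fold change of -4.99 (SE 0.58), which is 31.8-fold lower (limma adjusted p = 0.00533). On slides 1, 2 and 3 it differed by -4.67, -4.61 and -5.69.

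In all, 27 of 3197 tested gene probes passed limma's test at an adjusted p under 0.05, 18 higher and 9 lower in the mutant, and all 27 changed at least 2-fold. The 12 higher probes taken by the naming rule rose 8.01- to 56.1-fold, and the 8 lower ones besides CGR2615 fell 2.62- to 31.8-fold. For all 27 the mutant arrays lay on 1 side of the wild-type arrays. Such separation was found for 9.68% of the 2964 probes measured on all arrays, where chance gives 10% for arrays that can be exchanged freely. Arrays that share a slide cannot, and the 3 other splits that part all slides separated 1.89% to 2.46%. The splits that keep slides whole separated 6.92% to 23.0%, some of them more than the real split. With the slide as a block, 53 gene probes passed, 32 higher and 21 lower, and 49 of these changed at least 2-fold. With the authors' series matrix values 21 passed, 18 higher and 3 lower.

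The called gene probes lay close together in the numbering. With gaps of at most 5 numbers and 1 direction per group they formed 15 groups, 9 higher and 6 lower, and 5 groups of 3 or more called probes held 17 of the 27. With the slide as a block the 53 called probes formed 28 groups, and 8 groups of 3 or more held 31 of them. The lower group of this size had 4 consecutive probes, all called, which fell 4.47- to 4.81-fold. With the authors' series matrix values 0 of these 4 passed, at limma adjusted p of 0.0582 to 0.110. Their log2 fold changes were then -2.05 to -1.85, against -2.27 to -2.16 in the main fit. Among groups of this size, the one with the strongest rise had 3 of 5 tested probes called, CGR2927 among them, at 18.1- to 33.7-fold. In another higher group 5 of 6 probes were higher and 4 of them passed the test, at 8.01- to 12.1-fold. The remaining groups of this size held 3 consecutive called probes each, which rose 5.08- to 8.45-fold and 5.50- to 9.51-fold. The first of these kept 2 of its 3 calls in 5 of the 6 omissions of 1 array, with limma adjusted p up to 0.183, and the group of 4 called higher probes kept 3 without wild-type replicate 2. CGR2574, CGR2615 and CGR3090 were each the only called probe of their group.

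**Figure D2:**
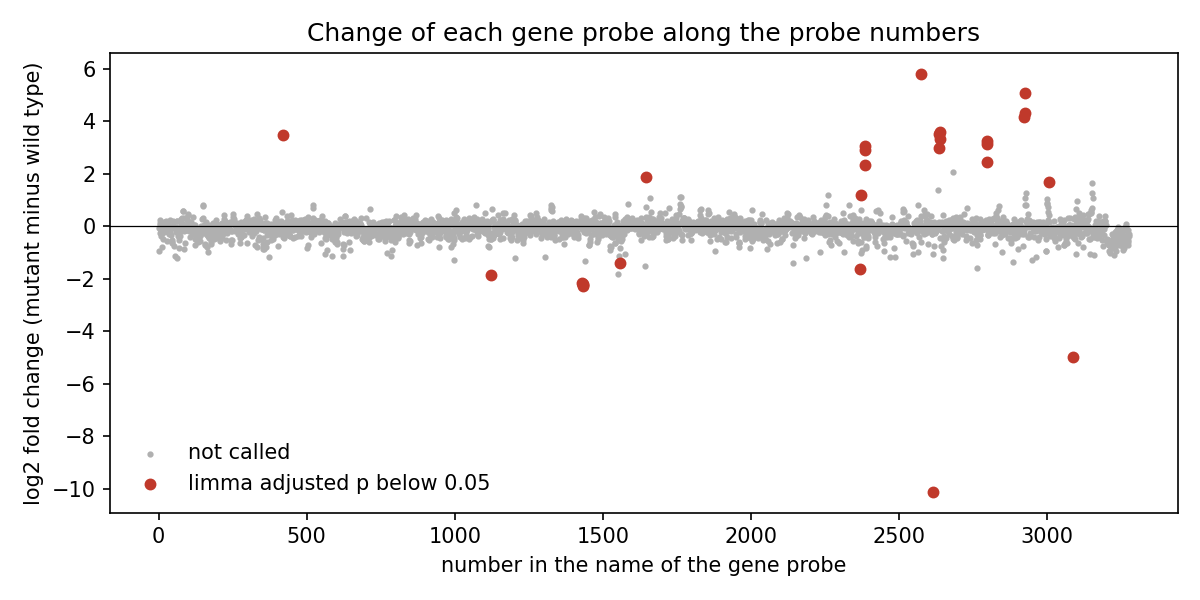
Log2 fold change of mutant minus wild type (y axis) of the 3197 tested gene probes against the number in the probe's name (x axis), with the 27 probes under an adjusted p of 0.05 in red. The lowest point is CGR2615, drawn at its measured value though it is not well above background in the mutant. The other called probes range from -4.99 to 5.81, and several stand in stacks at neighbouring numbers.

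The called tiling probes lay in runs as well. Wild-type levels at adjacent numbers correlated by 0.81 in both series, so the probes of a run are not independent readings. How many genes a run covers is not known. Of 29809 tested, 106 passed limma's test, 91 higher and 15 lower, with 44 in the forward and 62 in the reverse series. At gaps of at most 5 they formed 13 blocks, 10 higher and 3 lower, of which 8 held 3 or more called probes and 2 a single one. Gaps of at most 10 gave the same counts, and gaps of at most 2 gave 19 blocks, 13 higher and 6 lower. The block with most called probes lay in the reverse series, where 25 of 28 probes passed, with a median rise of 23.9-fold (13.2 to 67.0), and all 28 were higher. The top of that range is a probe near background in the wild type, at -7.46. Where all 6 arrays had to be well above background, 23 of the 25 stayed called. The log2 fold changes were then 3.72 to 5.22. Another reverse block had 19 of 20 probes called at a median of 8.84-fold, and a forward block had 18 of 22 at 11.5-fold. A forward block of 19 probes was lower throughout, with 10 called at a median of 4.85-fold lower. With the slide as a block 110 tiling probes passed, of which 84 were among the 106. The calls kept under the block were 21 of the 25, 18 of the 19, 14 of the 18 and 5 of the 10 in these blocks, in the same order. With no filter on dim probes they were 14, 18, 14 and 2, and of the 10 in the lower block 2 passed with array median scaling and 0 with the series matrix. Without wild-type replicate 3 the 4 blocks kept 18, 14, 9 and 0 calls, and without any other single array at most 2, 0, 0 and 0. The calls ended while the log2 fold changes stayed between 3.19 and 6.69, 2.50 and 3.61, 2.86 and 4.36, and -2.55 and -1.996 over all alternatives. The count of 106 depended on each array. Without wild-type replicate 1, 2 or 3 it was 5, 6 or 58, and without mutant replicate 1, 2 or 3 it was 4, 5 or 6.

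A pair of consecutive forward tiling probes was lost in the mutant as CGR2615 was. Both lay above the 75th percentile in the wild type, at 0.85 and 0.75, and were at least 365-fold and 340-fold lower. Their neighbours 1 number before and after differed by -1.23 (SE 0.41) and -1.02 (SE 0.41) and did not pass. All 7 tested probes among the 10 after the pair were lower, from -0.63 to -2.13, as were all 9 tested among the 10 before it, from -0.08 to -1.23, against 68.1% of all tested tiling probes. Relative to tiling probes of the same wild-type level the medians were -1.02 after and -0.24 before the pair. None of these passed limma's test (0 calls), and 4 after the pair and 1 before it had an unadjusted p under 0.05. A further 14 tiling probes were well above background on all wild-type arrays and on no mutant array. These were dim in the wild type too, at -5.79 or less.

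**Figure D3:**
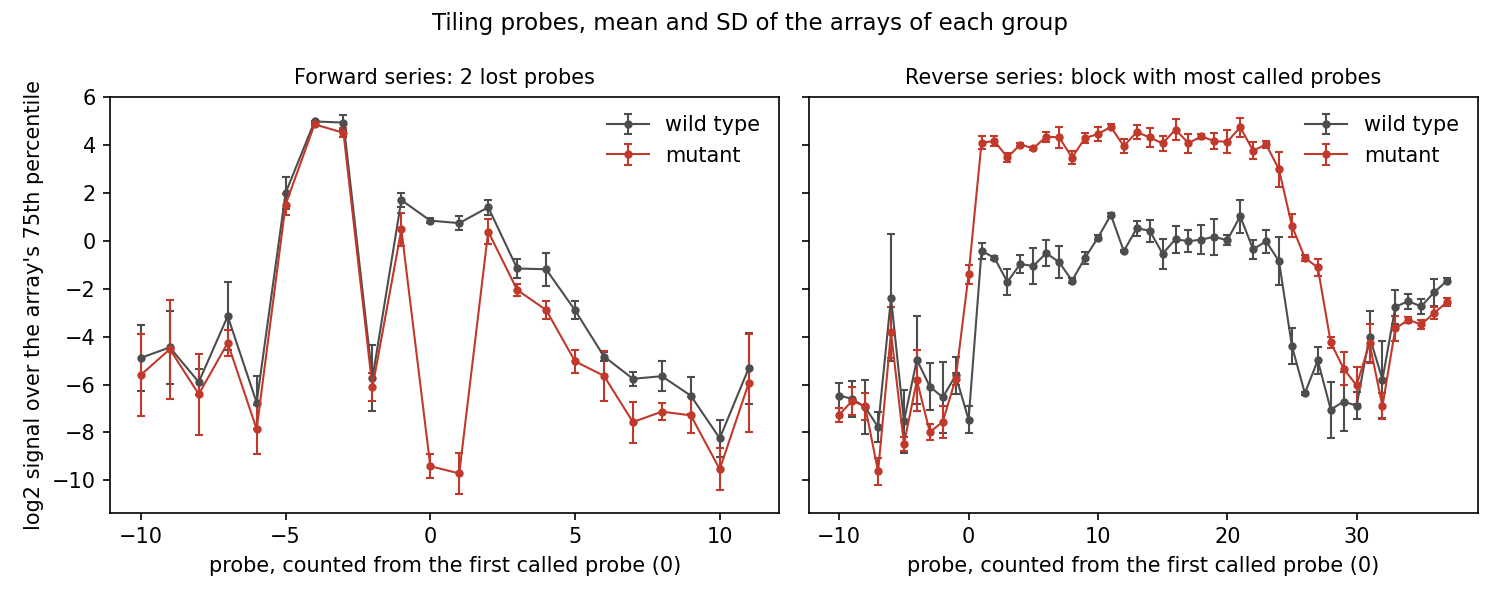
Log2 signal relative to the array's 75th percentile (y axis, mean and SD of the arrays of a group) of consecutive tiling probes, counted from the first called one (x axis), for the wild type (grey) and the mutant (red). On the left, 2 probes of the forward series drop in the mutant alone, and on the right the mutant lies above the wild type over all 28 probes of a reverse block.

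Of the 15 "ic" probes, 2 had all mutant arrays below all wild-type arrays. The first stood at 1.59 ± 0.25 in the mutant against 2.94 ± 0.35 in the wild type (SD, n = 3 each), a difference of -1.35, with -0.87, -1.57 and -1.61 on slides 1, 2 and 3. The other stood at 1.65 ± 0.07 against 1.82 ± 0.09 (SD, n = 3 each), a difference of -0.17, with -0.20, -0.03 and -0.29. For both, the exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow, and 0.75 after Benjamini-Hochberg adjustment over the 15 probes, so neither passed. Apart from the first, the 14 others differed by at most 0.46.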

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

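The tiling test with all its alternatives, the grouping by number and the omission of slide 3 were chosen after seeing the data. CGR2615, CGR2574, CGR2927 and CGR3090 kept their direction and stayed under the threshold in all 63 values from the alternatives that could test them, with adjusted p up to 0.0453. CGR2615 is not tested where a probe must be well above background on all 6 arrays. None of the 27 called gene probes changed sign in the 16 alternatives (0 changes). Of them, 14 stayed called in all 16 and 19 in each omission of 1 array. CGR2615 is not among the 14, since it was called in 15 of 16, all that could test it. Numbers of called gene probes without 1 array were 20 to 27.

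With the replicate block, here the same as the slide, 53 gene probes passed, 32 higher and 21 lower, and all 27 were among them. The authors' series matrix values gave 3 lower gene probes. They move the median of all gene probes from -0.05 to 0.12. Array median scaling moves it to 0.09 and still gave 8 lower gene probes, against 9 in the main fit. The "ic" probe that differed most was lower under all scalings tried.

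The tiling count moved more. It was 70 with no filter on dim probes (4 lower), 171 with trend and robust (44 lower), 2 without slide 3 (0 higher, 2 lower), and 4 to 58 without 1 array (2 to 56 higher, 2 lower each time). Lower tiling probes numbered 24 with the block, 7 with array median scaling and 2 with the series matrix. The cause was not tested.

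The mean of a gene's probes was not run, since each gene probe stands alone, and the gene list alternatives were not run for want of names. Signal over background limits the lost probes to bounds.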

Other observations

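Of the tests in this part, the distance between spots and the ends of the tiling series were fixed before their results were seen, and all others after.

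The gene probes numbered above 3200 were lower in the mutant as a set. Of 77 tested, 76 had a log2 fold change below 0, against 58.1% of the other gene probes, and their median was -0.54, against -0.03 for the 77 tested probes numbered just before them. None passed limma's test, with or without the slide as a block (0 in both), and 31 had an unadjusted p under 0.05. The place of the step was chosen from the plot of fold changes along the numbers. Of 3044 other stretches of as many probes, 0 had a median as low, the lowest being -0.23, but a stretch picked for being low cannot test chance this way, which stays open. Dim probes as such read lower on the mutant arrays. For the dimmest 1093, 1093 and 1087 gene probes of slides 1, 2 and 3 the medians were -0.15, -0.43 and -0.06. Against probes of the same wild-type level the set was still lower on slides 1, 2 and 3, with medians of -0.29, -0.59 and -0.51. The value nearest 0 (-0.2876) passed a cut-off that was set after it was seen. How far such medians spread for other stretches was not measured, and the set was picked for being low, so a dim-probe effect stays open. If the set were a separate stretch of DNA whose transcripts all fell, the last 1% of the forward tiling series could be lower too, yet it differed from probes of the same level by -0.04044. That argues against this reading as far as the tiling series ends on the same stretch, which the files do not say.

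The called gene probes at neighbouring numbers were weighed against 3 explanations. In a permutation test of 10000 random placements of the 27 calls, at most 4 fell into groups of 3 or more, against 17 observed (p = 0.0001, the smallest these placements can give). A local defect of the slide would need neighbouring spots, but spots of different probes in a group lay a median of 176.9 spots apart, against 157.6 for random pairs of gene spots. Neighbouring genes read together from 1 strand may be the reason. The called tiling probes, placed by relative number, matched the grouped gene probes more often than circular shifts did, at a share of shifts under 0.05, in 2 of 10 combinations of tolerance and counting direction, with shares of shifts from 0.0275 to 0.2884. The match pooled both series and did not ask for 1 strand, so it cannot tell this reason from a shared order alone. With the result also resting on the tolerance and direction chosen, and with no coordinates, this reason stays open. Within each series, probes at adjacent numbers had similar levels: across probes, their wild-type levels correlated by 0.42 for gene probes and 0.81 for both tiling series. This sets each series against itself, so it does not show that gene and tiling probes share 1 order.

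The loss of CGR2615 was weighed against failed spots, a deleted segment and a deletion of another gene. With the mutant taken at no less than the lowest signal well above background, each of its spots on each slide fell by at least 7.862 (log2), which failed spots would not give on 3 slides. A deleted segment may account for it. In the forward tiling series 2 consecutive probes at high wild-type level were lost in the same way. With no coordinates, this pair is not placed at CGR2615. The arrays read RNA, so they cannot tell a deleted segment from one that is no longer transcribed, and this reason stays open. Whether such a segment would be gntR1, or rshA as the design text has it, cannot be told apart, because 0 probe identifiers are named by the reference table.

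The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For gene probes the real split gave 27 calls and the highest other split 9, with 1 split as large as the real one, itself. With the slide as a block there are 4 such splits, again too few: the real one gave 53 calls and the highest other 0, with 1 as large. For tiling probes the real split gave 106 and another gave 4830, so that 2 splits were as large. That split sets the wild-type array of slide 1 and the mutant arrays of slides 1 and 2 against the rest. The split that exchanges the arrays of slide 2 also keeps slides 1 and 3 whole and gave 0. Among gene probes these splits gave 4 and 0 calls and separated 22.2% and 23.0% of probes. The counts do not tell slide, array and sample apart, and the cause was not tested. Among splits that part all 3 slides, the highest other gave 0. The blocked tiling count is 110, with 84 of the 106 among them.

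On slide 2 the tiling probes of the mutant array differed from those of the wild-type array by a median of -0.53, with -1.81 among the dimmest 12278 probes and -0.003 among the brightest 12287. The dimmest 12268 and 12227 tiling probes of slides 1 and 3 were lower too, by medians of -0.43 and -0.05. Before scaling, the 5th percentile of the log2 tiling signal of the wild-type array of slide 2 was 1.85 (forward) and 1.88 (reverse) above the mean of the other wild-type arrays. Brightness of the whole array enters this difference, since the 75th percentile of the signal was 4004 on this array and 3947 and 1812 on the others. It does not account for the gap to the wild-type array of slide 1, whose 75th percentile was close. There the forward 5th percentile was 3.85, against 5.28 on slide 2. On the linear scale its negative control spots had a median of 3.58, against 3.93 and 7.52 there.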
